A study of Sesuvium portulacastrum with 18 samples.

How the data were processed

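RNA was measured in Sesuvium portulacastrum, a halophyte (a plant that grows on saline ground), whose seedlings were raised from stem cuttings in liquid medium. At 15 days the plants were moved to control medium and collected at once (0 h), or moved to medium with 250 mM NaCl and collected 8 h or 24 h later, per the labels' protocols. Shoots and roots were profiled apart, with 3 biological replicates at each of 3 times, which makes 9 libraries per tissue and 18 in all. Total RNA was made into libraries with a kit that keeps the strand, per the labels' protocols. No unstressed plants stand beside the 8 h and 24 h sets, so time since the change of medium, hour of harvest and salt vary together.

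The files held 2 tables per tissue. The first table held estimated counts per transcript, deposited as whole numbers by the authors. The submitters' processing notes name Trimmomatic, kallisto 0.45 and edgeR 3.40.1, without saying which step each did. Because kallisto is a tool that estimates counts, the values were treated as estimated counts and rounded, which changed nothing. Any earlier rounding step is not given in the sources used here. The second table, whose name speaks of CPM, held a normalized signal that the authors deposited without describing its scaling. Its columns do not sum to the constant that plain CPM would give. Each value equals the CPM computed from the counts divided by 1 factor per library, and these factors equal, to rounding, the TMM factors (edgeR's trimmed mean of M values) of all transcripts with at least 1 count. These values are called normalized CPM here and served only to describe levels. How the transcripts were assembled, and whether the counting used the strand, is not given in the sources used here.

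Both tables name transcripts by an ID alone. The shoot and root IDs form separate sets, and the files pair no ID with a gene name or function. The lists of salt response genes and tissue markers chosen before the data were examined could therefore not be used, no gene list was tested, and root and shoot could not be compared transcript by transcript. Reads of near-identical transcripts can be split between IDs, so a single ID can carry part of a gene's signal. Every column was matched to 1 library (0 columns were left over).

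Each tissue was analysed alone in R 4.3.3. Transcripts were kept by edgeR's filterByExpr (version 4.0.16, minimum count 10, by group), which left 40220 of 99653 shoot transcripts and 34721 of 97620 root transcripts, with between 98.9% and 99.3% of each library's counts. After TMM scaling, 1 quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to the 9 libraries of a tissue, with a mean per time and no covariate. The contrasts were 8 h against 0 h, 24 h against 0 h and 24 h against 8 h, plus 1 test for any difference among the times. Tests were two-sided, and a transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all transcripts of that tissue and contrast. A standard error was taken as the size of the log2 fold change divided by the square root of its F statistic. The biological coefficient of variation was 0.169 in shoot and 0.184 in root.

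The transcripts named were fixed by a rule: for each of the 8 h and 24 h contrasts against 0 h, the 2 that rose most and the 2 that fell most by log2 fold change, among called transcripts whose 3 libraries lay beyond all 3 of the other group and whose lower group averaged at least 10 counts per library. Called transcripts with 0 counts in all 3 libraries of 1 group are given only as a number, since no fold can be stated against 0. A called 8 h change was said to have returned toward 0 h only where the 24 h against 8 h test was also called, in the opposite direction. The 2 tests share the 8 h libraries, whose noise enters them with opposite sign and so favours a return.

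Library totals ran from 10050233 to 15068602 estimated counts in shoot and from 8773677 to 13861135 in root. A count of 0 in 1 library allows up to 3 counts, or between 0.199 and 0.342 CPM, for counting error only. The tests were tried on simulated counts drawn with the real means, depths and spread, with 200 changed transcripts per run in 8 runs. For 8 h against 0 h the shoot test recovered 33.4% of 2-fold and 72.8% of 4-fold changes, and 8.41% of its calls were false, over 40220 transcripts. The root test recovered 39.5% and 76.5%, and 7.39% of its calls were false, over 34721 transcripts. The false share lay above the nominal level in both tissues. Each transcript was drawn independently, so the simulated libraries lacked the joint deviations from group means that the real ones show. The false shares hold for counts without such deviations, and the false share in the real data was not measured. These runs changed far fewer transcripts than were called in the data. Since the adjusted p depends on how many change, the recovered shares hold for such runs only.

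Replicates were compared before averaging. No 2 libraries of a group were identical, and their counts differed by between 3.21 and 20.5 times the sampling noise (chi-square per degree of freedom), so all were kept as separate replicates. Because both contrasts against 0 h share the same 3 control libraries, 20 simulated data sets with unchanged groups were made to give the correlation and covariance that this sharing alone produces. They held too few calls to give the overlap it adds to long lists. The 3 controls are too few to split in parts of at least 2. Alternatives covered scaling (DESeq2 size factors, library size alone), tool (DESeq2 1.42.0), filter, threshold, fold minimum, the replicate number as a block, fits of only the 2 groups compared, libraries thinned to the smallest total and each library left out in turn. After the data were examined, 5 more were added: sums over IDs that share a number, neighbouring IDs counted once, 2 covariates, and a fit without the 100 most abundant transcripts. Figures were drawn with matplotlib 3.10.9.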

Results

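Transcript levels were measured in shoots and roots of Sesuvium portulacastrum seedlings before and during salt stress, to describe how a salt-tolerant plant responds early to NaCl. Each tissue had 3 libraries at 0 h (control medium), 3 after 8 h and 3 after 24 h in 250 mM NaCl. The shoot libraries held 10050233 to 15068602 estimated counts and the root libraries 8773677 to 13861135. Counts were found for 89295 shoot transcripts and 87369 root transcripts over the 9 libraries of each tissue. The transcripts carry IDs without gene names, so the changes are described by transcript, by abundance and by time. All fold changes and adjusted p-values come from edgeR's quasi-likelihood test with TMM scaling, and levels are the deposited normalized CPM as mean ± SD of 3 libraries.

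The shoot libraries at 8 h stood apart from those at both other times. Across tested shoot transcripts, log2 CPM correlated at a mean r of 0.909 between 0 h and 8 h libraries, 0.898 between 8 h and 24 h, and 0.944 between 0 h and 24 h, against 0.959 to 0.971 within a group. In root the mean r was 0.929 between 0 h and 8 h, 0.944 between 0 h and 24 h and 0.943 between 8 h and 24 h, against 0.961 to 0.967 within a group. These correlations run across transcripts, which are not independent replicates. In shoot, the first principal component held 46.3% of the variance and set the 8 h libraries against all others. In root, the first 2 components held 31.7% and 20.6% and set the 3 times apart.

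**Figure D1:**
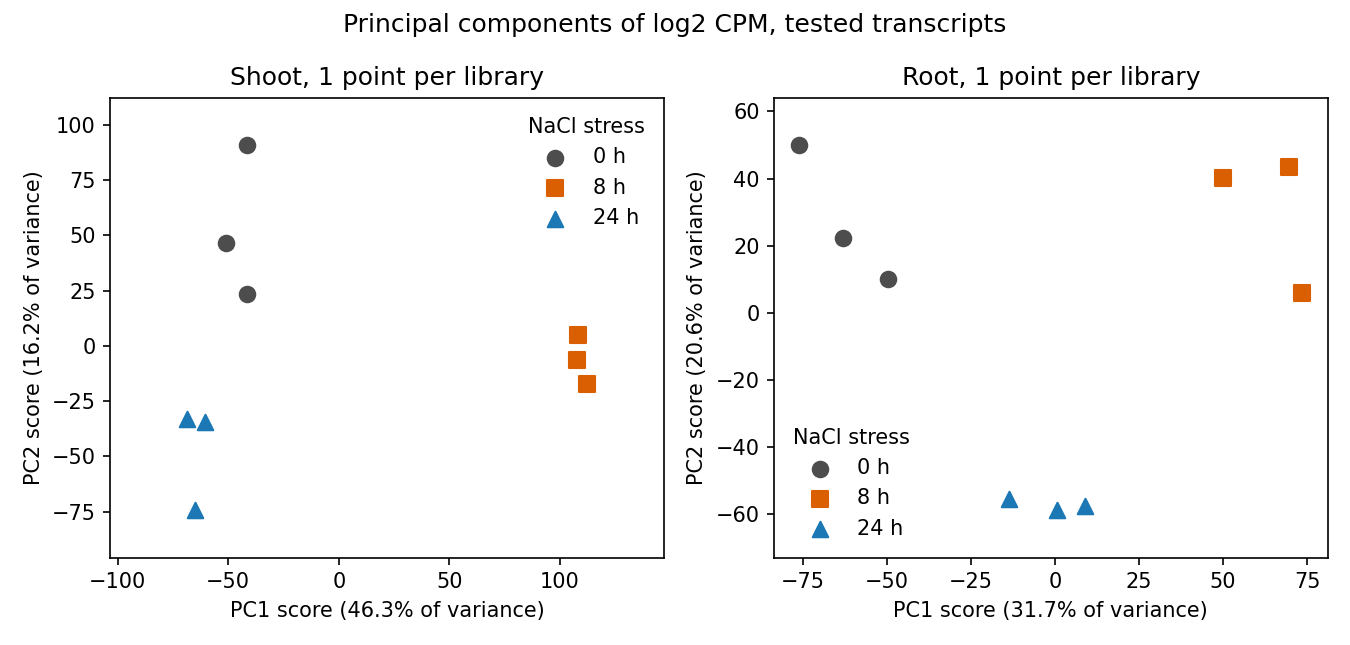
Scores of the 9 shoot and 9 root libraries on the first 2 principal components of log2 CPM, with 1 point per library, coloured and shaped by hours of NaCl stress. Shoot 8 h libraries lie at PC1 scores from 107 to 112, while shoot 0 h and 24 h libraries lie below -41; the root libraries form 3 groups by time.

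After 8 h in NaCl, shoots showed large rises and deep falls of abundant transcripts. S_Transcript_122046.p1 rose from 37.3 ± 10.2 to 1240 ± 131 CPM (log2 fold change 5.04, SE 0.22, adjusted p = 1.12e-08), and S_Transcript_25513.p1 rose from 4.34 ± 0.996 to 140 ± 6.16 CPM (4.99, SE 0.18, adjusted p = 3.15e-09). S_Transcript_709.p1 went from 1019 ± 151 to 4.67 ± 0.596 CPM and fell by 7.78 on the log2 scale (SE 0.29, adjusted p = 4.59e-09). S_Transcript_47518.p1 went from 257 ± 40.5 to 0.797 ± 0.376 CPM and fell by 8.33 on the log2 scale (SE 0.23, adjusted p = 3.72e-10). With the share of counts in each library's own 10 most abundant transcripts as a covariate, the log2 fold changes of S_Transcript_122046.p1, S_Transcript_25513.p1 and S_Transcript_709.p1 were 6.56, 5.92 and -9.19. The most abundant shoot transcript, by counts over all 9 libraries, fell too, from 17337 ± 2862 to 3849 ± 313 CPM (log2 fold change -2.18, SE 0.12, adjusted p = 6.3e-08).

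In total 10360 of 40220 tested shoot transcripts (25.8%) changed between 0 h and 8 h, of which 4279 rose and 6081 fell. At least 2-fold changes numbered 1753 up and 3268 down, and at least 16-fold changes 69 up and 202 down. With library size alone as the scaling, which moves the median log2 fold change by 0.24, the split turned to 8743 up and 4108 down among 12851. It was 4382 up and 5986 down with DESeq2's size factors in edgeR, and 3895 up and 5675 down in DESeq2. The 6081 transcripts that fell held 44.7 ± 0.859% of all counts at 0 h and 24.8 ± 0.113% at 8 h, and the 4279 that rose held 11.4 ± 0.153% and 23.6 ± 0.318%. Among the 100 shoot transcripts with most counts over the 9 libraries 56 fell and 16 rose with TMM, 31 of them falling at least 2-fold. Of the 13407 tested transcripts of highest mean CPM 27.1% fell and 17% rose, against 5.31% and 4.94% of the 13407 of lowest mean CPM, where lower counts leave less power. Both rankings use all 9 libraries, most of them from 0 h and 24 h, so they favour transcripts that are low at 8 h. Part of the excess of falls may come from this. Among the called transcripts 12 had no counts at 0 h and 29 none at 8 h. Of all tested transcripts 41.3% had 8 h libraries wholly above or below the 0 h libraries, where chance gives 10%. With the share of counts in the 10 most abundant transcripts as a covariate, which itself went with time in shoot (5.93 ± 0.625% at 0 h, 3.31 ± 0.0227% at 8 h), 2689 transcripts were called.

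After 24 h, fewer shoot transcripts differed from 0 h, and the named ones were others than at 8 h. S_Transcript_86605.p1 rose from 17.5 ± 13.4 to 381 ± 172 CPM (log2 fold change 4.44, SE 0.65, adjusted p = 0.00224), with 14.6 ± 13.1 CPM at 8 h. S_Transcript_86606.p2, whose number is the next one, rose from 3.2 ± 1.94 to 49.1 ± 22.9 CPM (3.95, SE 0.61, adjusted p = 0.00332). Without 0 h replicate 2 these log2 fold changes were 5.29 and 4.58. S_Transcript_38847.p1 went from 41.5 ± 3.74 to 1.82 ± 0.96 CPM and fell by 4.48 on the log2 scale (SE 0.73, adjusted p = 0.00432). S_Transcript_59556.p1 went from 105 ± 12.1 to 5.15 ± 2.04 CPM and fell by 4.33 on the log2 scale (SE 0.43, adjusted p = 0.00021). Both were already called at 8 h, S_Transcript_38847.p1 at 12.2 ± 12.4 CPM (log2 fold change -1.79, SE 0.58, adjusted p = 0.0411) and S_Transcript_59556.p1 at 9.1 ± 6.12 CPM (-3.55, SE 0.40, adjusted p = 3.7e-05).

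Between 0 h and 24 h 2842 of 40220 shoot transcripts (7.07%) changed, of which 1115 rose and 1727 fell, with 326 and 713 of these at least 2-fold. The transcripts that rose went from 6.13 ± 0.294% to 9.44 ± 0.265% of all counts, and those that fell went from 10.5 ± 0.511% to 6.4 ± 0.222%. Of the 100 most abundant transcripts 8 rose and 4 fell. The 24 h libraries lay wholly beyond the 0 h libraries for 25.2% of tested transcripts (chance 10%), and 6 called transcripts had no counts at 0 h and 6 none at 24 h. The count was 1741 without 24 h replicate 1, 1824 without replicate 2, 1878 without replicate 3 and 1688 in a fit of only the 2 groups. With the top-10 share as a covariate 770 were called, and S_Transcript_86605.p1 (adjusted p = 0.0903), S_Transcript_86606.p2 (0.0526) and S_Transcript_38847.p1 (0.0796) were no longer past the threshold in edgeR's test. Their log2 fold changes were then 4.54, 4.96 and -4.26, and their adjusted p stayed under 0.05 in the other alternatives run for single transcripts (all but the sums over IDs and the neighbours counted once), from 3.76e-15 to 0.00944, from 3.97e-13 to 0.0143 and from 9.42e-13 to 0.0238.

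Many 8 h changes in shoot had moved back by 24 h. S_Transcript_122046.p1 stood at 44.5 ± 10.8 CPM at 24 h (24 h against 8 h log2 fold change -4.77, SE 0.21, adjusted p = 1.34e-08), and S_Transcript_25513.p1 at 8.36 ± 2.08 CPM, still above 0 h (log2 fold change 0.94, SE 0.19, adjusted p = 0.0125). S_Transcript_47518.p1 reached 449 ± 31.2 CPM, above its 0 h level (0.81, SE 0.14, adjusted p = 0.00538). S_Transcript_709.p1 reached 686 ± 253 CPM, and its difference from 0 h did not pass the test (-0.56, SE 0.21, adjusted p = 0.138). The most abundant transcript returned to 20198 ± 928 CPM (24 h against 8 h 2.42, SE 0.12, adjusted p = 2.33e-08).

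Between 8 h and 24 h 11167 shoot transcripts changed, 6099 up and 5068 down with TMM, and 4346 up and 10181 down among 14527 with library size alone. Of the 10360 transcripts called at 8 h, 7270 (70.2%) moved back toward 0 h, 100 moved further, and 2990 showed no difference between 8 h and 24 h. Both tests use the same 8 h libraries, whose noise favours moving back over moving further, by an amount that was not measured. Of the 7270, 6437 were not called against 0 h at 24 h, 212 were still called in the 8 h direction and 621 in the opposite direction. The last number was 381 without 0 h replicate 2, and 406, 374 and 402 without 24 h replicates 1, 2 and 3. The 6081 transcripts that fell at 8 h held 45.2 ± 0.289% of counts at 24 h, and the 4279 that rose held 11.8 ± 0.227%. A set of 850 transcripts was late, differing at 24 h from both 0 h and 8 h without a call at 8 h, with 308 up and 542 down. With the top-10 share as a covariate the 24 h against 8 h count was 1249, and 1169 of 2689 transcripts called at 8 h moved back, which is no longer the larger part. The 24 h libraries lay wholly beyond the 8 h libraries for 43.4% of tested transcripts (chance 10%).

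**Figure D2:**
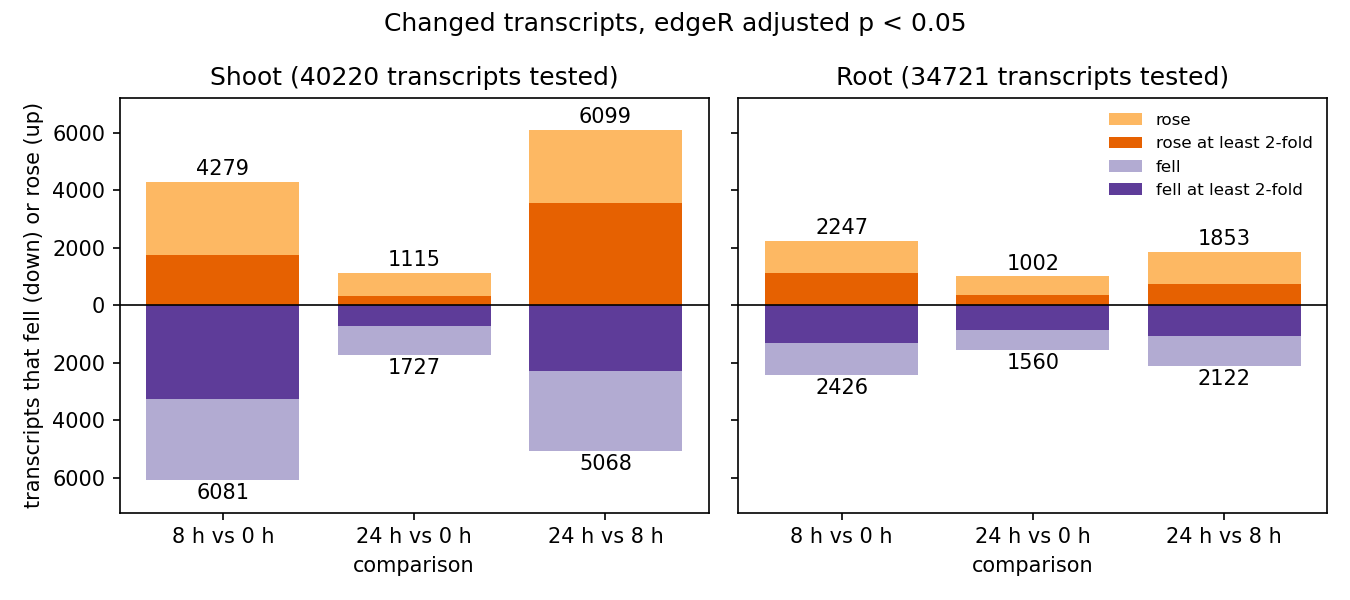
Transcripts that rose (above 0) or fell (below 0) in each comparison at adjusted p under 0.05, with the darker part of each bar for those changed at least 2-fold, in shoot (left) and root (right). Shoot counts against 0 h are 4279 up and 6081 down at 8 h, and 1115 up and 1727 down at 24 h; with library size alone as the scaling the shoot 8 h split turns to 8743 up and 4108 down, and the 24 h against 8 h split to 4346 up and 10181 down.

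In roots after 8 h the largest named rise was that of R_Transcript_3401.p1, from 1.19 ± 0.776 to 132 ± 39.9 CPM (log2 fold change 6.74, SE 0.46, adjusted p = 3.77e-06). R_Transcript_269055.p1 rose from 1.12 ± 0.414 to 38.1 ± 10.9 CPM (5.03, SE 0.40, adjusted p = 8.68e-06). R_Transcript_38667.p1 went from 126 ± 46.6 to 2.87 ± 0.458 CPM and fell by 5.43 on the log2 scale (SE 0.43, adjusted p = 8.85e-06). R_Transcript_97920.p1 went from 50.4 ± 15.7 to 1.61 ± 0.382 CPM and fell by 4.98 on the log2 scale (SE 0.43, adjusted p = 1.52e-05).

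At 8 h 4673 of 34721 tested root transcripts (13.5%) differed from 0 h, 2247 up and 2426 down, with 1122 and 1314 of these at least 2-fold, and 62 and 89 at least 16-fold. The transcripts that rose went from 8.01 ± 0.318% to 14.9 ± 1.52% of all counts, and those that fell went from 14.5 ± 0.167% to 7.84 ± 0.0596%. Of the 100 root transcripts with most counts over the 9 libraries 11 rose and 15 fell. Each library's own 100 most abundant transcripts, a set that can differ by library, held 18 ± 2.34% of all counts at 0 h and 18.1 ± 3.34% at 8 h (two-sided exact permutation p = 1, n = 3 per group, smallest possible p 0.1). The 8 h libraries lay wholly beyond the 0 h libraries for 30.4% of tested transcripts (chance 10%), and 13 called transcripts had no counts at 0 h and 46 none at 8 h. Without 8 h replicate 2 the count was 3081, and with the first component of the libraries' deviations from their group means as a covariate it was 7149.

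After 24 h, R_Transcript_269055.p1 was again among the largest rises in root, at 25.0 ± 11.5 CPM (log2 fold change 4.43, SE 0.40, adjusted p = 7.66e-05). R_Transcript_70507.p1 rose from 8.04 ± 1.53 to 109 ± 68.9 CPM (3.78, SE 0.49, adjusted p = 0.000862) and had been called at 8 h as well, at 102 ± 50.4 CPM (3.68, SE 0.49, adjusted p = 0.000344). R_Transcript_97919.p1 went from 65.8 ± 20.3 to 3.06 ± 2.43 CPM and fell by 4.46 on the log2 scale (SE 0.39, adjusted p = 6.55e-05). R_Transcript_97920.p1, with the next number, stood at 2.82 ± 2.3 CPM and fell by 4.20 on the log2 scale (SE 0.40, adjusted p = 0.000114). Without 24 h replicate 2 the log2 fold changes of this pair were -5.29 and -5.06, and without 24 h replicate 3 that of R_Transcript_70507.p1 was 3.12.

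At 24 h 2562 of 34721 root transcripts (7.38%) differed from 0 h, 1002 up and 1560 down, with 358 and 855 of these at least 2-fold, and 18 and 92 at least 16-fold. Those that rose went from 4.12 ± 0.312% to 6.8 ± 0.298% of all counts, and those that fell went from 10.2 ± 0.227% to 5.54 ± 0.211%. Among the called transcripts 8 had no counts at 0 h and 54 none at 24 h. The 24 h libraries lay wholly beyond the 0 h libraries for 27.2% of tested transcripts (chance 10%). The count was 1346 without 0 h replicate 3, 1282 without 24 h replicate 1 and 1432 without 24 h replicate 3. It was 4353 without the filter on low counts and 4948 with the first component of the deviations as a covariate.

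In root some of the named 8 h changes moved back by 24 h and others showed no difference between the times. R_Transcript_269055.p1 showed no difference between 8 h and 24 h that passed the test (log2 fold change -0.61, SE 0.29, adjusted p = 0.226), nor did R_Transcript_97920.p1 (0.79, SE 0.51, adjusted p = 0.398). R_Transcript_3401.p1 fell by 3.64 on the log2 scale between 8 h and 24 h (SE 0.36, adjusted p = 5.75e-05), to 10.4 ± 4.72 CPM, still above 0 h (3.11, SE 0.49, adjusted p = 0.0026). R_Transcript_38667.p1 rose to 28.7 ± 16.5 CPM (3.29, SE 0.43, adjusted p = 0.000393), still below 0 h (-2.15, SE 0.34, adjusted p = 0.00298).

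Between 8 h and 24 h 3975 root transcripts changed, 1853 up and 2122 down with TMM, and 1986 up and 1804 down among 3790 with library size alone. Of the 4673 called at 8 h, 2101 (45.0%) moved back toward 0 h, 50 moved further, and 2522 (54.0%) showed no difference between the times, which does not show that they were equal. Here too the shared 8 h libraries favour moving back over moving further. Of the 2101, 1796 were not called against 0 h at 24 h, 214 were still called in the 8 h direction and 91 in the opposite direction. The last number was 60, 43 and 27 without 0 h replicates 1, 2 and 3, 55 without 8 h replicate 2, and 41, 52 and 43 without 24 h replicates 1, 2 and 3. Without 0 h replicate 2, 1969 of 3810 moved back, the larger part, so which of the classes was larger depended on that library. Without 0 h replicate 3, 1537 of 3144 moved back, the smaller part. The late set held 627 transcripts, 239 up and 388 down. Without 8 h replicate 2 there were 2083 changed between 8 h and 24 h and 1172 that moved back, and the first of these counts was 2552 without 24 h replicate 1. With the first component of the deviations as a covariate the counts were 6104 and 3333.

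**Figure D3:**
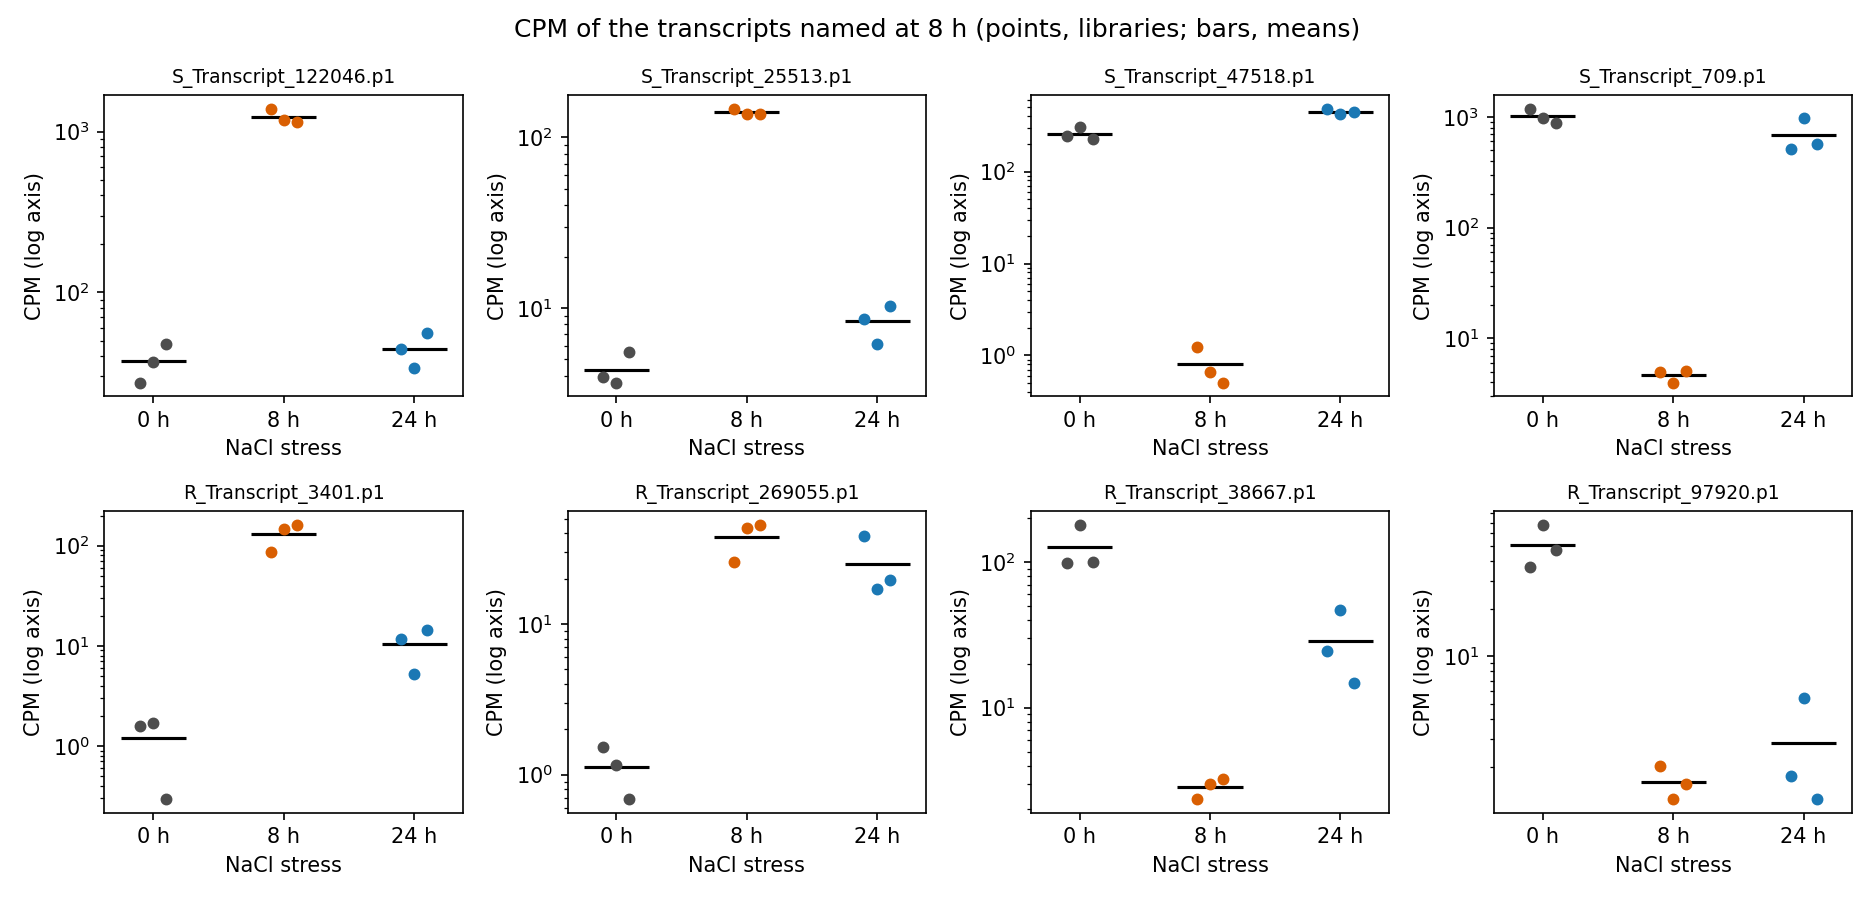
Normalized CPM (log axis) of the 8 transcripts named at 8 h against hours of NaCl stress, in shoot (upper panels) and root (lower panels), with 1 point per library and a bar at the mean of 3. S_Transcript_122046.p1 averages 37.3 CPM at 0 h, 1240 at 8 h and 44.5 at 24 h, while R_Transcript_269055.p1 averages 1.12, 38.1 and 25.0 CPM.

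The transcripts called at both times went mostly in 1 direction in root and less uniformly in shoot, a difference between tissues that was not tested by transcript. In shoot 1709 transcripts were called at both times, 314 up and 774 down at both, 211 up at 8 h and down at 24 h, and 410 down at 8 h and up at 24 h. Independent lists of these sizes would give 119, 261, 184 and 169. In root 1299 were called at both times, 455 up, 753 down, 57 up then down and 34 down then up, against 64.8, 109, 101 and 70.01 for independent lists. Simulated unchanged groups that share the controls gave 0 transcripts called at both times in each of 20 simulations per tissue, but with at most 5 calls at either time, so this 0 does not measure what shared controls add to lists of this length. Part of the excess over independent lists may come from the shared controls, which were too few to split. The shoot overlap was 1087 without 0 h replicate 2, and 1119, 1099 and 1107 without 24 h replicates 1, 2 and 3, while the root overlap was 739 without 0 h replicate 3, 767 without 24 h replicate 1 and 832 without 24 h replicate 3. Among fits that left out 1 library, calls in opposite directions were as few as 374 in shoot (without 24 h replicate 2) and 27 in root (without 0 h replicate 3). At adjusted p under 0.01 they were 198 in shoot and 17 in root, against 373 and 531 in the same direction. With a 2-fold minimum they were 90 and 9, against 341 and 615 in the same direction. Both settings are stricter by construction. With the top-10 share as a covariate the shoot overlap was 248, of which 35 went in the same direction and 213 in opposite directions, against 1088 and 621 without it. That share went with time in shoot, so this fit does not decide the split. With the first component as a covariate the overlap was 2654 in shoot and 2606 in root.

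Over all tested transcripts the log2 fold changes at 8 h and 24 h correlated at 0.22 in shoot, where shared controls alone gave 0.508 in simulation, and at 0.621 in root, where they gave 0.499. Their covariance was 0.123 in shoot against a simulated 0.0736, and 0.346 in root against 0.0715. Taken between different control libraries, the 24 h change per unit of 8 h change was 0.0346 ± 0.0386 in shoot and 0.475 ± 0.0733 in root (mean ± SD over the 3 libraries at 24 h). These SDs cover the 24 h libraries alone, since the 3 values of a tissue share its 0 h and 8 h libraries. The two-sided exact permutation p for the difference between tissues was 0.1, the smallest that 3 against 3 libraries can give, so this design could not test the difference at 0.05. For the same reason as the SDs, this p leaves out the noise of the 0 h and 8 h libraries, so it is no test between independent replicates.

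**Figure D4:**
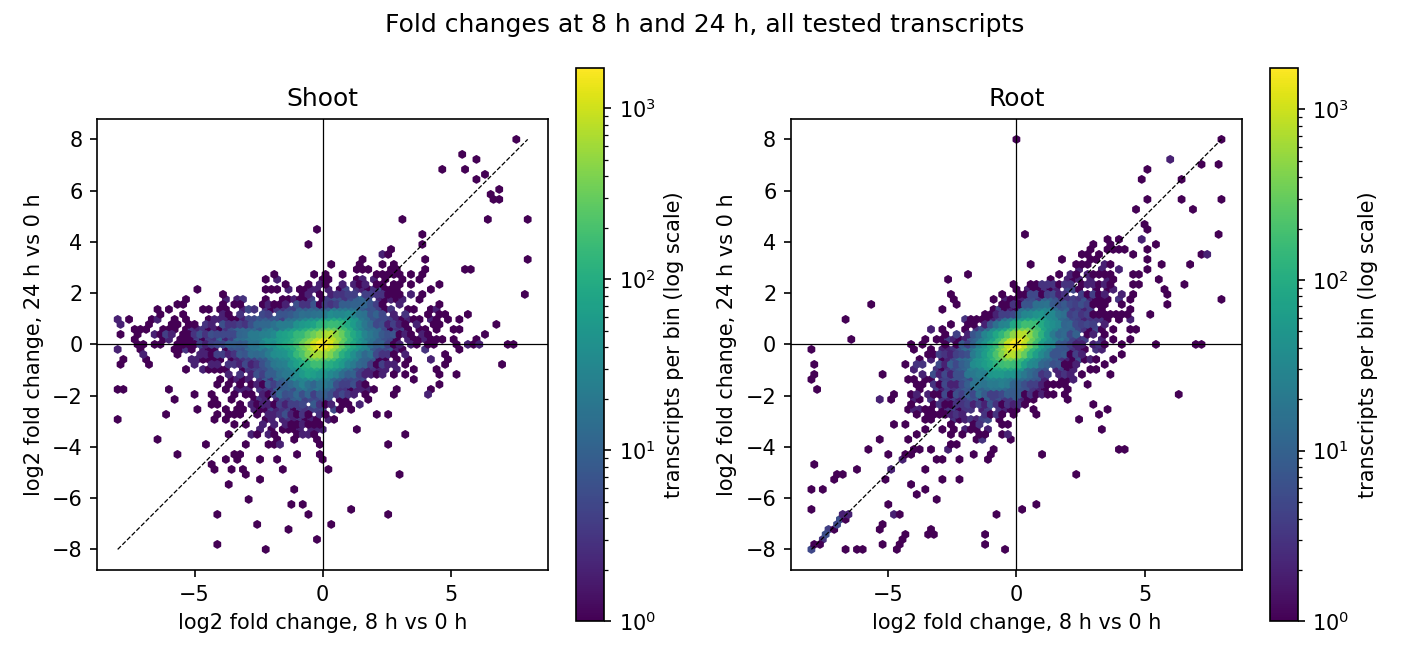
Log2 fold change at 24 h against log2 fold change at 8 h, both relative to 0 h, for all tested transcripts of shoot (left) and root (right), with colour for the number of transcripts per bin on a log scale, values beyond 8 drawn at the edge and a dashed line of equal change. Shoot transcripts spread along the 8 h axis (correlation 0.22), and root transcripts spread toward the dashed line (correlation 0.621).

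Over the whole time course 12761 shoot transcripts and 6302 root transcripts changed at some time. With all libraries thinned to the smallest total the 8 h counts against 0 h were 9689 in shoot and 4422 in root, and the 24 h counts 2669 and 2411. In shoot, each library's own 100 most abundant transcripts held 19.8 ± 1.37% of counts at 0 h, 15.6 ± 0.0689% at 8 h and 21.8 ± 0.197% at 24 h. The two-sided exact permutation p was 0.1 for each stress time against 0 h, the smallest possible with n = 3. In root this share was 16.3 ± 1.69% at 24 h (exact permutation p = 0.4 against 0 h, n = 3). With the top-10 share as a covariate 5606 shoot transcripts changed at some time, and with the first component 9767 root transcripts did.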

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

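The tests of harvest hour and of abundant transcripts were chosen after the data were seen, and the test of depth before. Transcripts called against 0 h in opposite directions at 8 h and 24 h numbered 621 in shoot and 91 in root, and each also passed the test of 24 h against 8 h. That test follows nearly by construction from opposite calls against the same 0 h libraries and adds no separate evidence. The shoot number was 381 without 0 h replicate 2, and 406, 374 and 402 without 24 h replicates 1, 2 and 3. The root number was 60, 43 and 27 without 0 h replicates 1, 2 and 3, 55 without 8 h replicate 2, and 41, 52 and 43 without 24 h replicates 1, 2 and 3. With a 2-fold minimum the numbers were 90 in shoot and 9 in root, and at adjusted p under 0.01 198 and 17. Other settings raised them, to 1022 in shoot with the first component of the deviations as a covariate. Without the filter on low counts they were 743 in shoot and 175 in root. Independent lists of the same sizes would give 184 and 169 shoot transcripts for the 2 opposite orders, against 211 and 410 found, and 101 and 70.01 in root, against 57 and 34 found. Shared 0 h libraries alone make opposite calls rarer than in independent lists, so these numbers do not give the value without an effect.

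The wider pattern is that the shoot libraries at 8 h lay far from those at 0 h and 24 h, with 10360 transcripts called at 8 h (2689 with the share of the 10 most abundant as a covariate, which went with time and so decides nothing). With library size alone as the scaling, leaving out the 100 most abundant transcripts moved the median log2 fold change from 0.24 to 0.16. The calls went from 12851 (8743 up and 4108 down) to 11402 (6818 up and 4584 down). The total stayed within 1.5 times, which argues against a few abundant transcripts taking the counts as the whole cause of the number of calls with this scaling. The split between directions did move, so the test leaves their part in that split open. Library depth would have brought the ratio of 8 h to 24 h calls under 1.5, but with all libraries thinned to 1 total the ratio was 3.63, against 3.65 before. The hour of harvest stays open: the 24 h change per unit of 8 h change was 0.0694 in shoot after simulated noise was removed and 0.0346 between different control libraries (0.549 and 0.475 in root), as a daily rhythm would give if the plants of the 3 times entered the medium at 1 hour, and as a short-lived salt response would also give. The design has no unstressed plants at 8 h, so rhythm and salt cannot be told apart, and a biological response to 250 mM NaCl may account for the pattern but remains a hypothesis.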

How the results depend on the processing

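The 2 covariates and the settings on neighbouring IDs, summed IDs and the 100 most abundant transcripts were chosen after seeing the data. Of 276 alternative values of 12 counts, 219 lay within 1.5 times of the reported count and 57 outside. Of 320 alternative fold changes of named transcripts, 317 kept direction and threshold side, 3 only direction (top-10 share as covariate) and 0 reversed. Picking the largest called changes in these libraries nearly ensured this. Counts follow in the order 8 h against 0 h, 24 h against 0 h, 24 h against 8 h, any time, called at both times, and moved back by 24 h. At adjusted p under 0.01 the shoot counts were 6559, 1033, 7418, 8192 and 571 (moved back stayed within 1.5 times), and the root counts 2474, 1010, 1869, 3176, 548 and 1029. With a 2-fold minimum they were 5021, 1039, 5826, 5803, 431 and 3556 in shoot and 2436, 1213, 1818, 2959, 624 and 958 in root. Both settings are stricter by construction. With the share of the 10 most abundant transcripts as a covariate the shoot counts were 2689, 770, 1249, 5606, 248 and 1169. That share went with time in shoot (3.31% at 8 h, 5.93% at 0 h and 7.02% at 24 h), so the covariate takes up part of the time effect. With the first component of the libraries' deviations as a covariate, which is built from the spread it then removes, shoot had 4385 (24 h against 0 h) and 2654 (both times), and root 7149, 4948, 6104, 9767, 2606 and 3333. A fit of only the 2 groups gave 1688 for shoot 24 h against 0 h. No filter on low counts gave 4353 for root 24 h against 0 h and 2308 for both times, and the cause was not tested. Leaving out each library in turn gave 1741 to 2633 for shoot 24 h against 0 h (lowest without 24 h replicate 1, then 1824 and 1878 without replicates 2 and 3) and 1087 to 1539 for shoot both times (lowest without 0 h replicate 2, then 1099, 1107 and 1119 without 24 h replicates 2, 3 and 1). In root it gave 3081 to 4712 for 8 h against 0 h, 2083 to 4318 for 24 h against 8 h and 1172 to 2094 for moved back (each lowest without 8 h replicate 2, with 2552 for 24 h against 8 h without 24 h replicate 1). It gave 1282 to 2550 for root 24 h against 0 h (lowest without 24 h replicate 1, then 1346 without 0 h replicate 3 and 1432 without 24 h replicate 3) and 739 to 1333 for root both times (lowest without 0 h replicate 3, then 767 and 832 without 24 h replicates 1 and 3). Fewer libraries leave less power by construction. Over the 9 pairs of libraries that share a replicate number, the correlation of deviations ran from -0.161 to 0.0649 in shoot (mean -0.0386, other pairs 0.0193) and from -0.108 to 0.23 in root (mean 0.0556, other pairs -0.0277), where 3 of 9 passed 0.1. Of the 9 libraries 0 in shoot and 6 in root correlated best with their own number. The numbers were not taken as pairs, since the criterion was a correlation over 0.1 in every pair, but the root values leave a shared number open as a hint from the data. With the number as a replicate block 9259 shoot and 4865 root transcripts were called at 8 h, and the block moved no count by over 1.5 times. The shoot counts came close to that line, with 1906 for 24 h against 0 h (2842 without the block) and 1146 for both times (1709 without it). Other groupings of the 6 libraries of a contrast make 10 splits, too few for a share under 0.05. The real splits gave 10360, 2842 and 11167 calls in shoot and 4673, 2562 and 3975 in root, 1 of 10 splits each time, and the highest other split gave 0 by edgeR (at an unadjusted p under 0.05, at most 1551, 2690, 1164, 3309, 4411 and 2016, against 14542, 8661, 15010, 9204, 7542 and 8231 for the real splits). For any time, 1 of 100 splits drawn gave as many as the real 12761 in shoot (highest other 61) and the real 6302 in root (highest other 622), which excludes chance at 0.05. Sums to gene level and tests of gene lists were not run, since the IDs name no gene. With 200 changed transcripts per run, simulation recovered 33.4% of 2-fold changes in shoot and 39.5% in root at 8 h. Adjusted p depends on how many change, so these shares are not the sensitivity of the real contrasts. Thinning to the smallest total left 9689 and 4422 calls at 8 h, and the effect of more depth was not tested.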

Other observations

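The reading of the test on neighbouring numbers and the correlations with library make-up were chosen after the results were seen. The counts with neighbours taken once and the fit without the 100 most abundant transcripts were added after the data were examined. Changed transcripts came in neighbours by number. S_Transcript_86605.p1 and S_Transcript_86606.p2 rose together at 24 h in shoot, and R_Transcript_97919.p1 and R_Transcript_97920.p1 fell together in root. Of 5819 shoot pairs with consecutive numbers, 725 had both members called at 8 h, where 386 would be expected by chance, and 91.2% of these went in 1 direction, against 57.9% in the highest of 1000 random draws. In root 232 of 4790 pairs were both called at 8 h (86.8 by chance), 88.4% in 1 direction against at most 63.8%. Reads of 1 gene split between near-identical transcripts may give such a share, since each ID would then carry part of that gene's change, and so may separate forms of 1 gene that change together. The IDs do not settle which. With neighbours of 1 direction counted once the 8 h counts were 9489 in shoot and 4436 in root. No biological explanation was tested.

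Libraries of different groups deviated together from their group means in both tissues, more so in root. The mean absolute correlation of deviations between root libraries of different groups was 0.104, against at most 0.00849 in 20 simulations without such a structure. In shoot the observed value was 0.0685, against at most 0.00977 in 20 simulations. With all libraries thinned to 1 total the root value was 0.104. Thinning keeps each transcript's expected share of the counts, so it could hardly have lowered this correlation. Library depth stays open, and in root the first component of the deviations went with total counts (given below). A few abundant transcripts taking the counts stay open: without the 100 most abundant transcripts the value was 0.104 as well, but a correlation across transcripts ignores a shift common to all of them, so that test could not have lowered it and decides nothing. No biological explanation was tested.

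The first component of the deviations held 28.6% of their variance in root and went with the share of counts in the 10 most abundant transcripts, centred by group, over the 9 libraries (size of Pearson's r 0.847, exact permutation p = 0.0139, adjusted over 4 relations 0.0278; Spearman's rho 0.85, exact permutation p = 0.0231, adjusted 0.0463; r 0.849 without the 2 libraries farthest from the median). In shoot r was 0.905 (exact permutation p = 0.0324, adjusted 0.0432; rho 0.933, exact permutation p = 0.0231, adjusted 0.0463; r 0.86 without 2 libraries). With total counts the size of r was 0.78 in root (exact permutation p = 0.0139, adjusted 0.0278) and 0.547 without 2 libraries. The size of rho was 0.767 (exact permutation p = 0.037, adjusted 0.0494). In shoot the size of r was 0.857 (exact permutation p = 0.0602, adjusted 0.0602) and 0.705 without 2 libraries. That of rho was 0.717 (exact permutation p = 0.125, adjusted 0.125). Each r and rho given here is a size without sign, so no direction is stated. Total counts and top-10 share ran opposite ways in root at 8 h (8773677 and 12.6% in replicate 1, 13861135 and 5.82% in replicate 3). They rose together in shoot at 0 h (10050233 and 5.25% in replicate 1, 15068602 and 6.47% in replicate 3). The other groups showed no such order. The 2 measures were not tested apart.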
